A study of Mus musculus with 4 samples.

How the data were processed

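Fibroblasts were grown from WT and podoplanin-deficient mouse embryos of the strain given as C57BL6/J, cultured in serum, and depleted of endothelial and blood cells by magnetic selection against CD31 and CD45, per the labels' protocols. Total RNA was extracted, copied to single-stranded cDNA, fragmented, end-labelled with biotin and read on 1-colour arrays, per the labels; the probe annotation is that of an Affymetrix gene array. There were 4 arrays, 2 per genotype. The labels call the samples biological replicates; how many embryos or litters each culture came from, and the stage of each embryo, are not given in the sources used here.

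The deposited values are intensity per probe set on a linear scale. They were made with RMA, per the submitters' processing notes, a method that corrects background, normalises quantiles across arrays and summarises the probes of a set on the log scale. Its version, software and settings are not given in the sources used here. The 4 arrays were deposited in 2 tables of 24679 probe sets each, whose values differed by at most 0.005, and the series value table was used. RMA leaves no detection calls or background levels, so no gene was called absent; low values are compressed towards a floor, and fold changes of dim genes are therefore underestimated. Quantile normalisation sets the arrays' distributions nearly equal, so a shift shared by most genes could not be seen. The number of arrays limits the precision.

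Log2 was taken with no pseudocount and no further normalisation or filter. Probe sets were named from the platform annotation given with the series: 21354 had 1 gene symbol, 1275 several and 2050 were not listed there. Symbols were checked through Entrez identifiers against RefSeq genes of the assembly GRCm38.p6, where 21277 probe sets matched and 0 symbols changed. That table was otherwise used only for which genes neighbour each other, because the deposited tables name no genome build; chromosome and band are those of the deposited description of each probe set. For 893 symbols with several probe sets the one with the highest mean was kept, which gave 19751 genes. The 3325 other probe sets were tested apart from them, and 0 passed an adjusted p of 0.05 in limma, with 78 at an unadjusted p under 0.05.

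Pdpn KO was compared with WT with limma 3.58.1 in R 4.3.3 (lmFit on a 2-group design, eBayes, two-sided, Benjamini-Hochberg over all genes; threshold adjusted p 0.05). The ± after a log2 fold change is its standard error, with a median of 0.127 over genes, and n is 2 arrays per genotype. Such a p-value borrows the spread of all genes: 4 arrays split 2 against 2 in only 3 ways, so no exact permutation test can pass 0.05. As no source says what separates the replicates, p-values measure the spread between these arrays, part of which can be technical. The 34 gene lists held 864 names, of which 805 were measured, and were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists; the result of 1 list is not reported here. Members' p-values were also adjusted over the list alone. Camera with an estimated correlation passed 0 lists. Fry, which asks whether a list's genes move on balance 1 way, passed 0 lists, and its mixed form, for change in either direction, also passed 0.

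The lists, the tests, the naming rule and the alternatives were fixed before the data were examined, apart from those said to be chosen later. The rule named Pdpn; genes past the threshold whose values do not overlap between genotypes, at most 12 per direction, and where fewer passed, up to 5 more per direction with the smallest unadjusted p, stated as not passing; up to 4 members with the smallest p from each list that passed; up to 2 of the brightest members of other lists; and Xist with the Y-linked genes. Predicted genes without a functional name were passed over.

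The fits were tested on simulated data drawn for the 19751 genes with the means and spread of these arrays and 200 changed genes in each of 20 simulations. Calls were made for 4.5% of genes changed by 1.5-fold, 72.3% by 2-fold, 98.5% by 4-fold and 100% by 16-fold. So many changed genes ease the adjustment for multiple tests, and fewer would be called where few genes change. An unchanged list passed an unadjusted p of 0.05 in camera in 2 of 20 simulations and a list raised by 0.2 in 20 of 20. Simulated genes varied independently, and same-numbered arrays shared no difference. These shares therefore do not show how the test behaves on lists whose genes vary together. The alternatives were the other deposited table, median centring, quantile normalisation, leaving out the dimmer 25% or 50% of genes, another prior for the spread, the mean of a gene's probe sets, the replicate number as a block, each array left out in turn, other thresholds, an equal-variance test on each gene alone without limma's prior, and other list tests. Figures were drawn with matplotlib 3.10.9.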

Results

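Gene expression was measured in mouse embryonic fibroblasts, primary mesenchymal cells grown out from embryos, that were wild type (WT) or lacked podoplanin (Pdpn KO). Podoplanin, encoded by Pdpn, is a transmembrane glycoprotein of fibroblasts, lymphatic endothelium and some epithelia that binds the platelet receptor CLEC-2 and the ezrin, radixin and moesin linkers of the actin cortex. The comparison asks which transcripts differ between fibroblasts with and without the protein. Each genotype had 2 arrays, called biological replicates in the labels, and 19751 genes were tested. The median RMA intensity of the arrays lay between 283 and 290, a closeness that RMA itself imposes. Across genes, the log2 values of WT replicates 1 and 2 correlated with r = 0.994 and those of Pdpn KO replicates 1 and 2 with r = 0.993. The correlation of WT replicate 1 with Pdpn KO replicate 1 was 0.996 and that of WT replicate 2 with Pdpn KO replicate 2 was 0.996, so arrays of the same genotype were no more alike than some arrays of different genotypes. Genes are not independent replicates, and these correlations only describe the arrays.

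Pdpn transcript was strongly reduced in both knockout cultures. Its intensity was 4486 and 3106 in the WT arrays and 179 and 201 in the Pdpn KO arrays, a 19.7-fold lower geometric mean. The log2 means were 11.87 ± 0.37 (SD, n = 2) in WT and 7.57 ± 0.12 (SD, n = 2) in Pdpn KO, and the log2 fold change was -4.30 ± 0.19 (SE), with a 95% interval from -4.76 to -3.84 (limma adjusted p = 0.00501). The gene, read by probe set 10518147 and placed on chromosome 4 in band E1, went from the 94.9 percentile of all genes in WT to the 38.4 percentile in Pdpn KO. The part of the transcript that the probe set covers, and the part removed in the targeted allele, are not given in the sources used here. With a test on each gene alone, without the spread that limma borrows from other genes, the log2 fold change of -4.30 had an adjusted p of 1.00, and 0 of the 19751 genes passed.

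Beyond Pdpn, 1 gene passed the threshold in the fit without a replicate block. Decr1, which encodes a mitochondrial enzyme that helps oxidise unsaturated fatty acids, was 3.73-fold lower in Pdpn KO, with intensities of 528 and 478 in WT and 128 and 142 in Pdpn KO. Its log2 fold change was -1.90 ± 0.12 (SE, n = 2 per genotype; limma adjusted p = 0.0266), read by probe set 10511679 on chromosome 4, band A2. In this fit no gene was higher in Pdpn KO at an adjusted p under 0.05. At an unadjusted p under 0.05, 296 genes were higher and 101 lower, where 988 would be expected by chance. That shortfall depends on the model. With the replicate number as a block, 1676 genes had an unadjusted p under 0.05 in limma, and 34 passed, 27 of them higher. Values of the genotypes did not overlap for 24.4% of genes, against 33.3% by chance with 2 arrays per group.

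The genes next in rank in each direction under the naming rule did not pass in the fit without a block, and their values are given as measured. Penk, the precursor of the enkephalin opioid peptides, read 719 and 543 in WT and 2290 and 1894 in Pdpn KO (log2 fold change 1.74 ± 0.17, SE; limma adjusted p = 0.203). Mme, the membrane endopeptidase neprilysin, which degrades enkephalins among other peptides, read 257 and 323 in WT and 813 and 794 in Pdpn KO (1.48 ± 0.14; limma adjusted p = 0.203). Serpinb10, a serine protease inhibitor (1.28 ± 0.14), Adgrg2, an adhesion G protein-coupled receptor (0.91 ± 0.12), and Anxa8, a calcium-dependent phospholipid-binding annexin (0.87 ± 0.11), had higher values in both Pdpn KO arrays, with limma adjusted p between 0.242 and 0.425. On the other side, Emcn, a sialoglycoprotein of endothelium, differed by -1.11 ± 0.16, Tnfrsf1b, a receptor for tumour necrosis factor, by -1.02 ± 0.13, Fbxo44, an F-box protein, by -0.88 ± 0.13, Miip by -0.75 ± 0.12 and the zinc finger gene Zfp985 by -0.71 ± 0.12, with limma adjusted p from 0.425 to 0.815. Zfp985 belongs to a family of closely similar genes, so its probe set can also read relatives. It has 2 probe sets, of which the brighter is given. Its log2 fold change ran from -0.80 to -0.61 with 1 array left out. Over all alternatives, which include the mean of its probe sets, it reached -0.38.

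**Figure D1:**
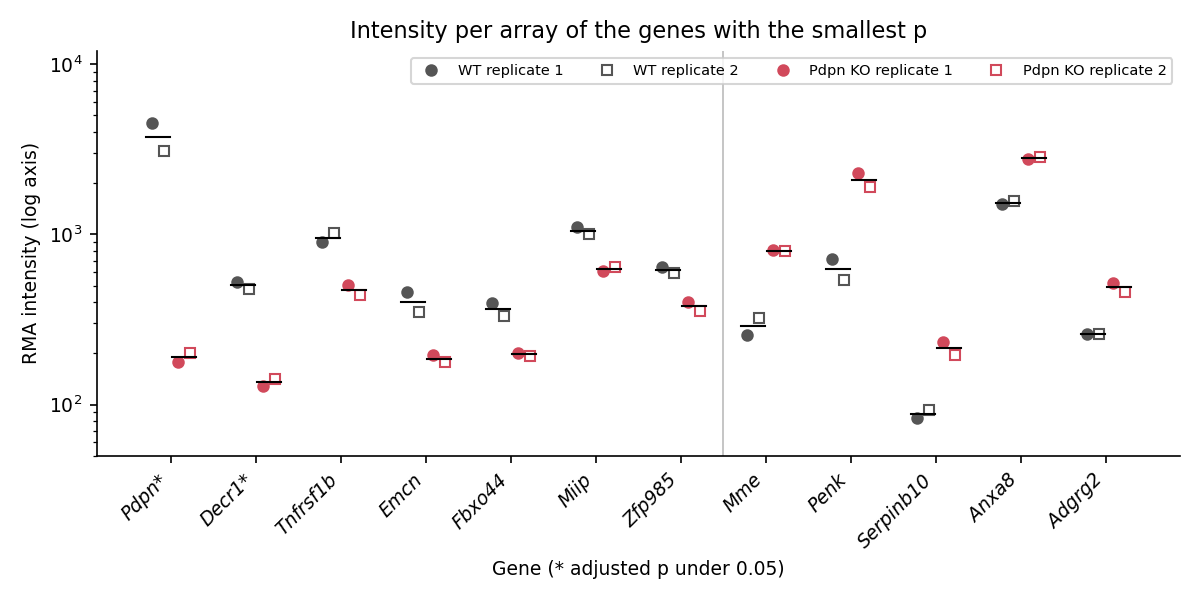
RMA intensity on a log axis in each of the 4 arrays for Pdpn, Decr1 and, in each direction, the 5 genes next in rank under the naming rule. Genes lower in Pdpn KO are to the left of the grey line and those higher to the right. Short black lines are geometric means of the 2 arrays, and asterisks mark a limma adjusted p under 0.05. Pdpn falls from 4486 and 3106 to 179 and 201, and Penk is at 719 and 543 in WT and at 2290 and 1894 in Pdpn KO.

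The number of genes called rested on how the spread was estimated, on the use of a replicate block and on single arrays. It was 9 (6 higher, 3 lower) with limma's robust, intensity-dependent prior, Penk, Mme, Serpinb10, Anxa8 and Tnfrsf1b among them, 0 with a test on each gene alone, and 5 without WT replicate 1, 53 without WT replicate 2, 100 without Pdpn KO replicate 1 and 50 without Pdpn KO replicate 2. Penk, Mme and Serpinb10 passed in each of the fits without 1 array, at adjusted p up to 0.0480, and Emcn, Tnfrsf1b, Anxa8 and Adgrg2 in those without either Pdpn KO array. Pdpn and Decr1 were among the calls in each of these limma fits, whereas Decr1 was not tested, and 1 gene was called, when the dimmer 50% of genes was left out. Without Pdpn KO replicate 1, the Pdpn KO array left was the 1 with the sex-linked pattern of female cells, described below. Both WT arrays had that of male cells, so genotype and sex could not be told apart there. In that fit Eif2s3y had a log2 fold change of -5.42 and Xist 5.11. The count was 34 (27 higher, 7 lower) with the replicate number as a block. Penk (limma adjusted p = 0.00359), Mme (0.0244), Serpinb10, Anxa8 and Adgrg2 then passed, higher. Emcn, Tnfrsf1b, Fbxo44 and Zfp985 passed, lower, at adjusted p up to 0.0458, and Miip did not pass. Same-numbered arrays did deviate together. The first principal component, the main axis of difference between arrays, held 58.8% of the variance. It placed WT and Pdpn KO replicates 1 at -16.6 and -14.3, and replicates 2 at 11.8 and 19.1. Number 2 against number 1 gave 10 calls in limma, and the remaining split of the arrays gave 0. The fit without a block counts that difference as spread, and the fit with a block has fewer values left to estimate spread. The labels do not say what arrays of the same number share.

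Genes of proteins that podoplanin is known to bind, and targets of transcription factors that respond to actin tension, showed no difference past the threshold between the genotypes with all genes tested. Among 13 podoplanin-binding proteins and linkers of ezrin, radixin and moesin, the median was 0.02 (limma camera adjusted p = 0.462). Msn, moesin, had a log2 fold change of -0.05 ± 0.11 (SE) and Bsg, basigin, 0.01 ± 0.11, while Cd9, a tetraspanin chosen after its values were seen, was the only one of the 13 with an unadjusted p under 0.05 (0.29 ± 0.11; limma adjusted p = 0.507, adjusted over the list alone). For 26 targets of SRF-MRTF and YAP-TEAD, the factors that respond to tension, the median was -0.04 (limma camera adjusted p = 0.262). Thbs1, thrombospondin, read 17583 and 17373 in WT and 16976 and 16735 in Pdpn KO, and Acta2, smooth muscle alpha-actin, had a log2 fold change of -0.03 ± 0.11. These targets passed, lower, without the dimmer 50% of genes (median -0.04, limma camera adjusted p = 0.0166) and with an intensity-dependent prior (limma camera adjusted p = 0.0279). Without WT replicate 2 their median was -0.10. The WT arrays differed too, by 0.06 in replicate 1 and -0.06 in replicate 2 from the WT mean. Small changes of single genes would rarely have been called: in simulated data with the spread of these arrays, 4.5% of 1.5-fold changes and 72.3% of 2-fold changes passed. Those data held 200 changed genes, some changed by 16-fold, which eases the adjustment for multiple tests, so the shares overstate what could be called where few genes change.

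Adhesion and matrix lists did not pass with all 4 arrays and all genes tested. The list of integrins and focal adhesion genes had a median of -0.03 over 34 genes (limma camera adjusted p = 0.412), with Actn4 at -0.03 ± 0.11 and Actn1 at -0.03 ± 0.11, both cross-linkers of actin. Adjusted over the list alone, 1 member passed against 0 over all genes tested: Itga2, a collagen-binding integrin chain chosen after its values were seen, was higher at 0.81 ± 0.15 (limma adjusted p = 0.0426 over the list). The adhesion list passed, lower, without the dimmer 50% of genes (median -0.03, adjusted p = 0.0166). Collagens and fibrous matrix had a median of 0.03 over 39 genes (adjusted p = 0.363), with Fn1, fibronectin, at -0.08 ± 0.12. Basement membrane components had -0.05 over 25 genes (0.431), with Nid1, nidogen, at -0.11 ± 0.13, and matrix proteases and inhibitors 0.03 over 27 genes (0.397), with Timp1, a metalloproteinase inhibitor, at 0.11 ± 0.11. The median of the collagen list was 0.15 without WT replicate 2 and 0.11 without Pdpn KO replicate 1. The list also differed within WT. From the WT mean, its median member differed by -0.14 in WT replicate 1 and 0.14 in WT replicate 2. In Pdpn KO replicates 1 and 2 it differed by -0.03 and 0.11, so genotype and replicate number cannot be told apart in those fits.

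Signalling, stress and immune lists likewise stayed short of the threshold of limma camera with all 4 arrays and all genes tested. The median log2 fold change was 0.08 for 29 genes of TGF-beta and BMP signalling (adjusted p = 0.0868), 0.06 for 32 Wnt genes (0.164), 0.09 for 34 chemokines and cytokines of lymphoid stroma (0.248), 0.05 for 33 interferon-stimulated genes (0.378) and 0.00 for 15 antigen presentation genes (0.536). Wnt5a, a secreted Wnt ligand, had -0.31 ± 0.11, and Ptgs2, the inducible cyclooxygenase, -0.14 ± 0.11. The median was -0.05 for 20 p53 and senescence genes (0.206), 0.01 for 17 Nrf2 targets (0.346), 0.04 for 25 genes of the unfolded protein and amino acid stress response (0.412), 0.03 for 26 genes of glycolysis and hypoxia (0.610), -0.02 for 18 cholesterol synthesis genes (0.773) and -0.03 for 17 imprinted and fetal growth genes (0.857). In this last list, Plagl1, an imprinted zinc finger gene chosen after its values were seen, was higher at 0.66 ± 0.12 when adjusted over the list alone (limma adjusted p = 0.0267), and 0 passed over all genes tested. The p53 list passed, lower, without the dimmer 50% of genes (median -0.05, adjusted p = 0.0166). Without WT replicate 2 the medians were 0.05 for TGF-beta and BMP, 0.15 for Wnt, 0.18 for stroma cytokines and -0.13 for p53. Without Pdpn KO replicate 1 they were 0.15 for Wnt, 0.12 for stroma cytokines and 0.12 for Nrf2 targets. In that fit they were 0.17 for the stress response, -0.17 for p53 and -0.15 for cholesterol synthesis. TGF-beta and BMP had 0.11 without Pdpn KO replicate 2, and Nrf2 targets 0.11 without WT replicate 1. Such fits leave replicate numbers unequal between the genotypes, and the lists also differed within WT. In WT replicate 2 the median member differed from the WT mean by 0.11 for Wnt and 0.07 for stroma cytokines. It differed by 0.07 for the stress response, 0.04 for TGF-beta and BMP, -0.05 for p53 and -0.06 for cholesterol synthesis. Only Nrf2 targets, at -0.04, had the opposite sign there.

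Markers of other cell types showed no shift of a whole list with all 4 arrays. The median was 0.00 for 17 markers of blood endothelium (limma camera adjusted p = 0.493), -0.03 for 9 of lymphatic endothelium (0.368), -0.04 for 20 of macrophages and other blood cells (0.478), -0.06 for 17 of epithelium (0.412), -0.06 for 13 of mesothelium (0.397), -0.01 for 26 of muscle (0.370), 0.04 for 19 of cartilage and bone (0.370), 0.05 for 15 of fat cells (0.431), 0.05 for 12 of pericytes and smooth muscle (0.466) and 0.00 for 19 of neural and Schwann cells (0.507). Adjusted over each list alone, 1 member passed in 3 of them, against 0 over all genes tested. These were Emcn in blood endothelium, lower (limma adjusted p = 0.00565 over the list), Stmn2, a neuronal stathmin, higher at 0.61 ± 0.11 (0.0272), and Msln, mesothelin, chosen after its values were seen, higher at 0.79 ± 0.16 (0.0240). In all, 8 of the 34 lists had a member past the threshold adjusted over the list alone, and 0 had one past it over all genes tested. The cartilage and bone list had a median of 0.11 without WT replicate 2 and 0.08 without Pdpn KO replicate 1. It also differed within WT, by -0.11 in replicate 1 and 0.11 in replicate 2 from the WT mean. In Pdpn KO replicates 1 and 2 its median member differed from the WT mean by -0.07 and 0.08. The direction of the test opposed the sign of the list's median for pericytes, neural cells and antigen presentation, and opposed the sign of its mean for epithelium, adhesion, basement membrane and fetal growth genes.

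**Figure D2:**
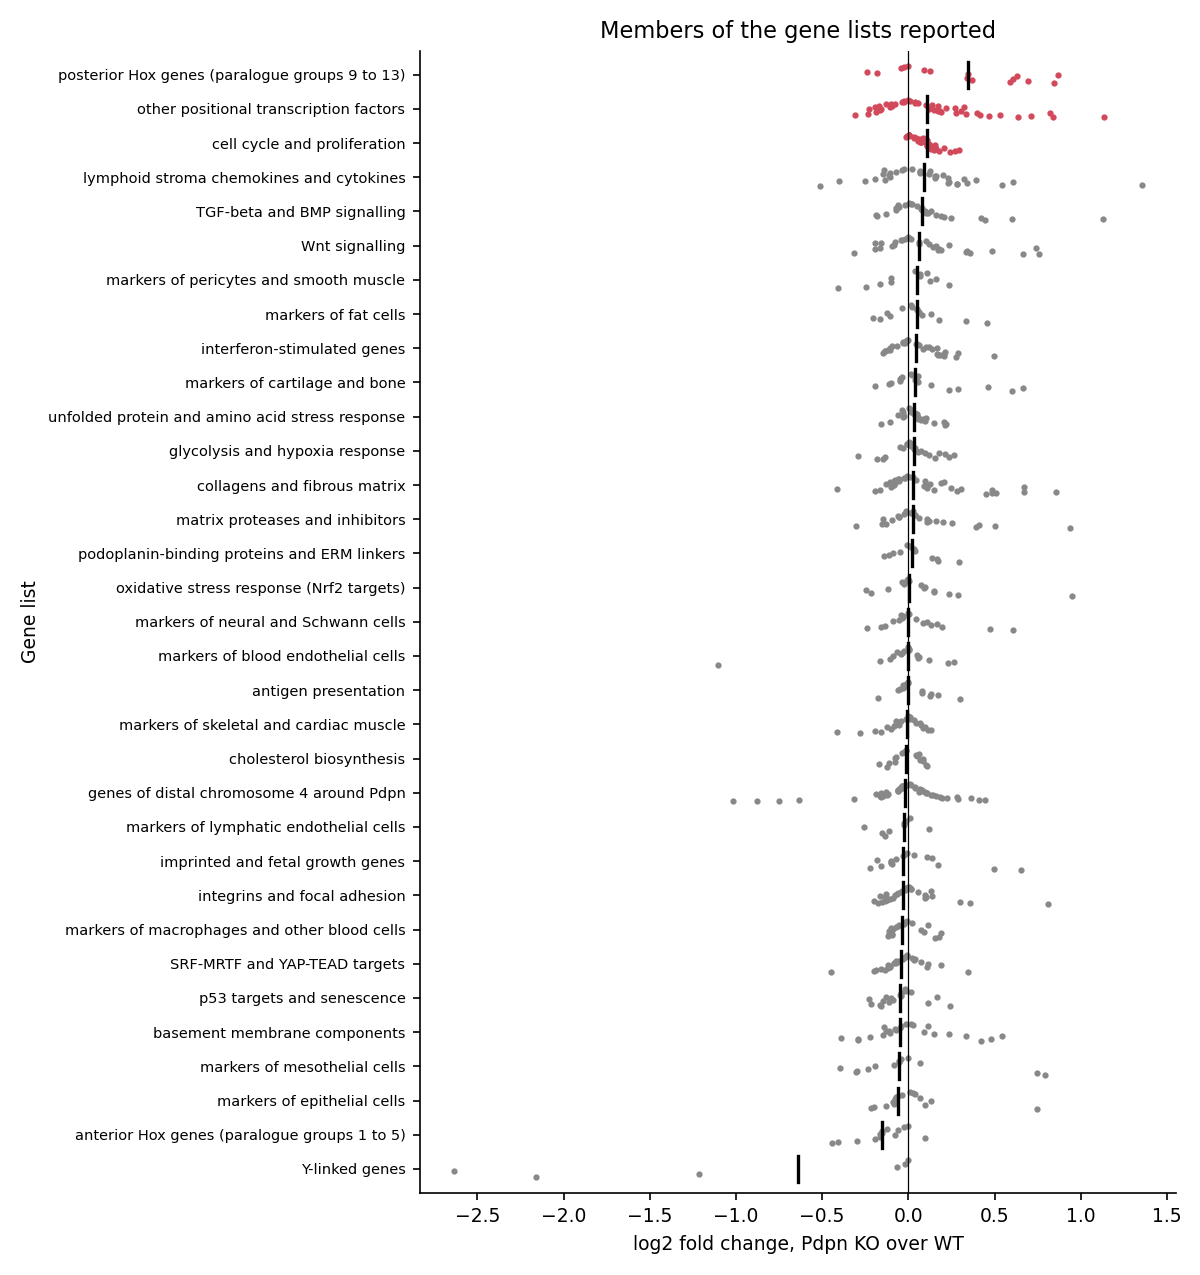
Log2 fold change, Pdpn KO over WT, of each measured member (dot) of the gene lists reported, with the list's median as a black line; lists past an adjusted p of 0.05 in limma camera with a preset correlation are red. The medians of the 3 red lists are 0.34, 0.11 and 0.11, and of the others only the Y-linked list at -0.64 and the anterior Hox list at -0.15 have medians beyond 0.10 in size.

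Posterior Hox genes were higher in Pdpn KO as a list with a preset correlation, by more in 1 array than in the other. Of 16 posterior Hox genes, which pattern the lower trunk and the distal limb, 11 had a higher mean in Pdpn KO, and the median log2 fold change was 0.34 (limma camera adjusted p = 2.16e-05 with a preset correlation, adjusted p = 0.813 with an estimated correlation). Hoxd10 read 295 and 309 in WT and 495 and 595 in Pdpn KO (0.85 ± 0.13, SE), and Hoxd12 187 and 214 against 275 and 330 (0.59 ± 0.14). Adjusted over the list alone, these 2 passed (limma adjusted p = 0.00865 and 0.0425), and 0 passed over all genes tested. Hoxa10 (0.70 ± 0.20) and Hoxa9 (0.37 ± 0.12) passed neither. With the replicate number as a block, Hoxd10 passed over all genes (limma adjusted p = 0.0365). Without Pdpn KO replicate 1, the log2 fold change was 0.98 for Hoxd10 and 0.99 for Hoxa10. The 2 Pdpn KO arrays did not move every member the same way. Hoxc10, chosen after its values were seen, had 1.15 without Pdpn KO replicate 1 and -1.21 without Pdpn KO replicate 2. Both Pdpn KO values lay above both WT values for 8 of the 16 genes, where 16.7% of single genes would do so by chance, though members can vary together. The size of the shift differed between arrays: the median member differed from the WT mean by 0.59 in Pdpn KO replicate 2 and by 0.08 in Pdpn KO replicate 1, and without Pdpn KO replicate 2 the median was 0.08 and the list did not pass (adjusted p = 0.452, in a range over all alternatives from 1.61e-20 to 0.895). In that array the median of 14 anterior Hox genes differed from the WT mean by -0.54, against 0.15 in Pdpn KO replicate 1. As a list the anterior genes had a median of -0.15 and did not pass (limma camera adjusted p = 0.0516), though it passed, lower, without WT replicate 2 (0.0160) and without Pdpn KO replicate 1 (4.49e-14). With all 4 arrays it also passed, lower, without the dimmer 25% of genes (0.0247), without the dimmer 50% (0.0166) and with an intensity-dependent prior (0.0279). Hoxa5 read 1181 and 1187 in WT and 1314 and 604 in Pdpn KO, and Hoxc5 1275 and 1246 against 1556 and 811.

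Other transcription factors of limb, face and body wall position were higher as a list with a preset correlation. Over 44 genes, 27 had a higher mean and 17 a lower one, with a median of 0.11 (limma camera adjusted p = 0.00143 with a preset correlation, adjusted p = 0.813 with an estimated correlation). The T-box factor Tbx5, a determinant of forelimb and heart, read 287 and 313 in WT and 786 and 555 in Pdpn KO (1.14 ± 0.18, SE). Shox2, a homeobox gene of the proximal limb, had 0.84 ± 0.11, Tbx18 0.71 ± 0.14, and Tbx15, a T-box gene of limb and skin mesenchyme, 0.63 ± 0.11. Adjusted over the list alone, these 4 genes passed (limma adjusted p from 0.0102 to 0.0222), and 0 passed over all genes tested. Tbx5 passed over all genes without WT replicate 2 (adjusted p = 0.0326), Pdpn KO replicate 1 (0.0193) or Pdpn KO replicate 2 (0.000190), and Shox2 without Pdpn KO replicate 1 (0.0187). Both Pdpn KO values lay above both WT values for 16 of the 44 genes, where 16.7% of single genes would do so by chance, though members can vary together. Without Pdpn KO replicate 2 the median was 0.04 and the list still passed (adjusted p = 0.0127), whereas without the dimmer 50% of genes it did not (adjusted p = 0.397); over all alternatives the adjusted p ran from 0.000178 to 0.813.

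**Figure D3:**
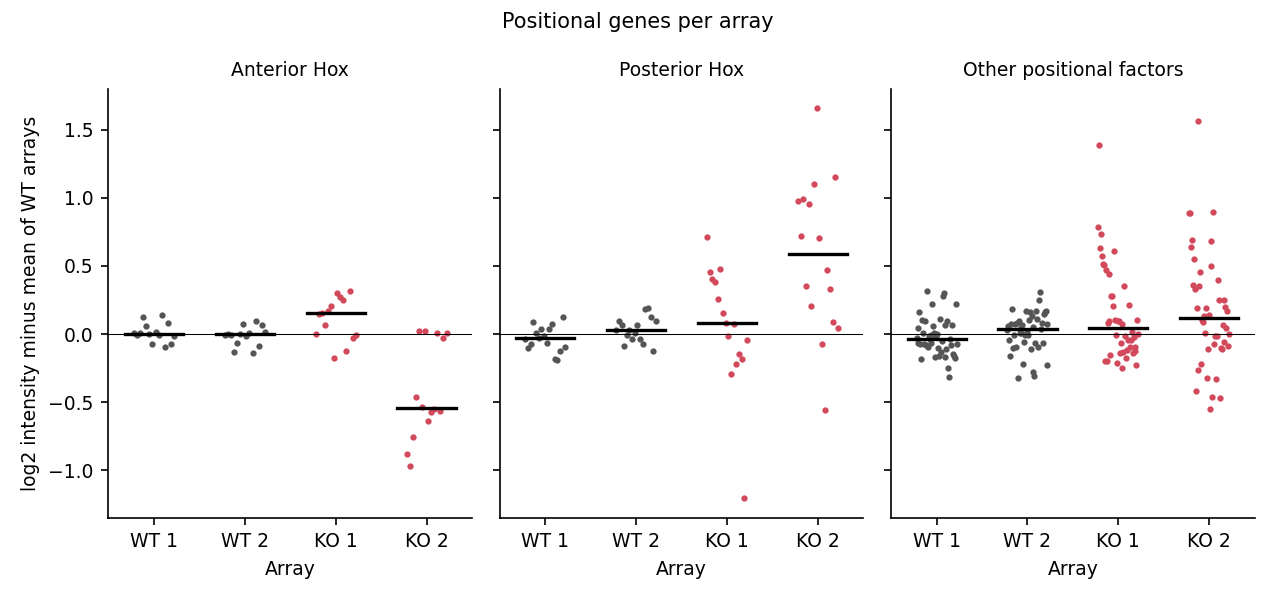
Log2 intensity minus the mean of the WT arrays for the members (dots) of 3 lists of positional genes in each array, with the median as a black line. Pdpn KO replicate 2 has the posterior Hox median at 0.59 and the anterior Hox median at -0.54, and Pdpn KO replicate 1 has them at 0.08 and 0.15.

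Cell cycle genes were slightly higher as a list, a call that rested on single arrays. Of 40 genes, 38 had a higher mean in Pdpn KO, with a median log2 fold change of 0.11 and none at an unadjusted p under 0.05 (limma camera adjusted p = 0.000475 with a preset correlation, adjusted p = 0.813 with an estimated correlation). Aurkb, a mitotic kinase, had 0.27 ± 0.13 (SE), Mcm3, of the replicative helicase, 0.30 ± 0.19, Nusap1, a spindle protein, 0.24 ± 0.11, and Ttk, a spindle checkpoint kinase, 0.18 ± 0.11. The median member differed from the WT mean by 0.20 in Pdpn KO replicate 2 and by 0.01 in Pdpn KO replicate 1. The call ended without Pdpn KO replicate 2 (median 0.0097, adjusted p = 0.928, test direction down) and without WT replicate 2 (median 0.06, adjusted p = 0.412), and over all alternatives the adjusted p ran from 5.32e-08 to 0.928.

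Genes near Pdpn on distal chromosome 4 were set out as a list because a targeted allele can carry neighbouring DNA of another strain. As a whole the list of 49 genes did not shift (median -0.02, limma camera adjusted p = 0.397). Adjusted over the list alone, 3 genes passed, and 0 over all genes tested: Tnfrsf1b at 900 and 1021 in WT and 506 and 442 in Pdpn KO, Fbxo44 at 397 and 333 against 202 and 194, and Miip at 1103 and 1006 against 609 and 646 (limma adjusted p = 0.00862 for each over the list). Srm, spermidine synthase, had 0.04 ± 0.12 and Pgd, of the pentose phosphate pathway, -0.12 ± 0.11.

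**Figure D4:**
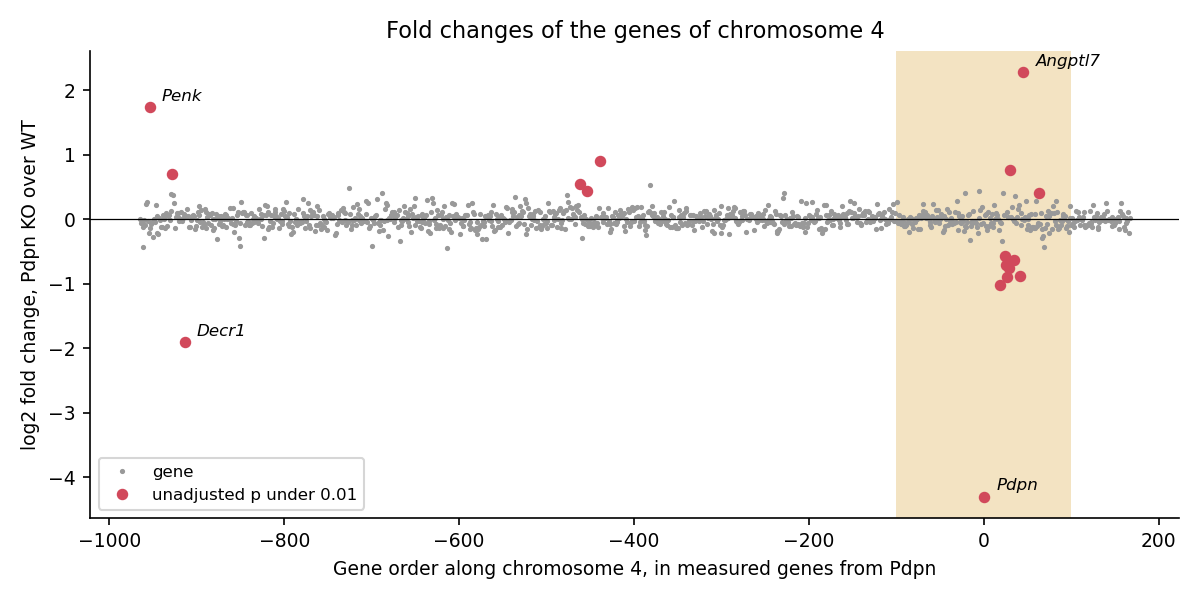
Log2 fold change, Pdpn KO over WT, of 1133 genes of chromosome 4 against their order from Pdpn, with genes at an unadjusted p under 0.01 in red and the 100 measured genes on each side of Pdpn shaded. Besides Pdpn, 10 red genes lie in the shaded span, 3 higher and 7 lower, and 6 lie elsewhere on the chromosome.

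Sex-linked transcripts differed between arrays rather than between genotypes. Xist, the RNA that coats the inactive X chromosome of female cells, read 48.6 and 57.4 in WT and 48.9 and 1831 in Pdpn KO. The Y-linked genes Eif2s3y, Uty and Kdm5d were bright in 3 arrays and dim in Pdpn KO replicate 2: Eif2s3y read 1534, 1474 and 1673 against 35.1, Uty 760, 758 and 799 against 36.0, and Kdm5d 597, 506 and 569 against 98.2. Usp9y, Zfy1 and Zfy2 stayed below 40 in all 4 arrays. The labels give the sex of all 4 samples as female. The Y-linked list had a median of -0.64 over 6 genes and did not pass (limma camera adjusted p = 0.0516); it passed without WT replicate 1 (0.0447), WT replicate 2 (0.00586) or Pdpn KO replicate 1 (1.72e-26), and its median was 0.06 without Pdpn KO replicate 2 (0.928). With all 4 arrays it passed, lower, with an intensity-dependent prior (0.0188) and, in a setting chosen after the data were seen, with names from the deposited descriptions added (median -1.22, adjusted p = 0.0119). Pdpn KO replicate 2, the array with this pattern, is also the one in which the posterior Hox and cell cycle shifts were larger.

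**Figure D5:**
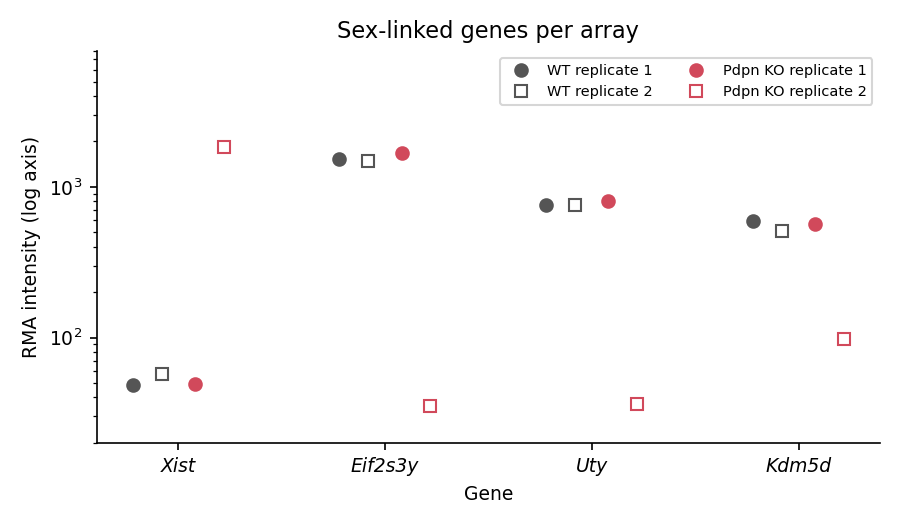
RMA intensity on a log axis of Xist and 3 Y-linked genes in each of the 4 arrays. Pdpn KO replicate 2 has Xist at 1831 and Eif2s3y at 35.1, and the other 3 arrays have Xist at 48.6 to 57.4 and Eif2s3y at 1474 to 1673.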

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

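Leaving out genes of the X and Y chromosomes and adding names from the deposited descriptions were chosen after seeing the data; the other settings were planned. Pdpn kept its direction in all 15 alternatives, with a log2 fold change from -4.57 to -4.03 when 1 array was left out, and passed in 14 of them with an adjusted p of at most 0.0480; it did not pass with an equal-variance test on each gene alone (-4.30, adjusted p 1.00), which has only 4 values to estimate each spread. Decr1 was called in 13 of its 14 alternatives, the exception being the same test. The number of genes called was 2 in 9 of 17 alternatives, 1 without the dimmer 50% of genes, which removes Decr1, 9 with the robust, trended prior, 0 with the test on each gene alone, and from 5 to 100 with 1 array left out. In those last fits the lone array is assumed to vary like the other pair, and replicate numbers are unequal between the genotypes. Without Pdpn KO replicate 1, genotype and sex pattern could not be told apart either. The cause of the larger counts was not tested.

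The labels give both genotypes replicate numbers 1 and 2 without saying what they share. With the number as a replicate block, 34 genes were called (27 higher, 7 lower; Penk, Mme, Hoxd10, Shox2, Crabp2, Angpt1, Mmp3 and Bmp4 among the higher), 1676 genes had an unadjusted p under 0.05 against 397 without it, and the count of lists stayed at 3. The difference between arrays 2 and 1 correlated across genes between the genotypes with r = 0.58. Number 2 against number 1 gave 10 calls, and WT 2 with Pdpn KO 1 against WT 1 with Pdpn KO 2 gave 0.

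The number of lists called was 3 in the fit reported, 7 without the dimmer 50% of genes and 6 with an intensity-dependent prior. It was 0 with an estimated correlation and 0 with fry, and it changed whichever array was left out. The cell cycle list turned in test direction without Pdpn KO replicate 2, at an adjusted p of 0.928, and its median ran from 0.0097 to 0.20 with 1 array left out; the cause was not tested. With all arrays, other settings brought 10 further list results and 17 further results of named genes past the threshold; for the other changes of count the cause was not tested. A change of sign in a value that passed in neither fit was not counted as a reversal, and 49 of the 86 named genes other than Pdpn kept their sign in every setting. Background signal was not used here, so how far dim genes lie above it is unknown.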

Other observations

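All tests of explanations in this part were chosen after the results were seen, and so were the genes named here that the naming rule does not cover.

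Single genes picked after their values were seen are given here without a test of any shared theme. Crabp2, an intracellular retinoic acid-binding protein, had a log2 fold change of 1.26 ± 0.18 (SE, n = 2 per genotype; limma adjusted p = 0.570), Prg4, lubricin, 1.31 ± 0.20 (0.570), Angpt1, angiopoietin-1, 0.83 ± 0.13 (0.570), and Mmp3, stromelysin, 0.94 ± 0.20 (limma adjusted p = 1.00). Bmp4, a bone morphogenetic protein, read 605 and 1366 in WT and 1410 and 2807 in Pdpn KO (1.13 ± 0.44, adjusted p = 1.00). None of these 5 genes passed over all genes in the fit reported, but Crabp2 did with the robust, intensity-dependent prior (adjusted p = 0.0465). Crabp2, Angpt1, Mmp3 and Bmp4 also passed with the replicate number as a block. With 1 array left out, Crabp2 passed without WT replicate 2 (0.00144), Pdpn KO replicate 1 (0.00185) or Pdpn KO replicate 2 (0.00343), and Prg4 without the same arrays (0.00367, 0.00556 and 0.000165). Angpt1 had a log2 fold change of 0.95 without Pdpn KO replicate 1, and Mmp3 1.19 without Pdpn KO replicate 2. Bmp4 had 1.72 without WT replicate 2 and 1.63 without Pdpn KO replicate 1. Within both genotypes Bmp4 was higher in replicate 2, so those fits mix genotype with replicate number. Cxcl12, a chemokine of stromal cells, read 3491 and 3783 in WT and 2909 and 2239 in Pdpn KO (-0.51 ± 0.15, adjusted over its list 0.398).

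For 4 positional genes, picked because they differed between the 2 knockout arrays and not tested as a group, the values were as follows. Tbx4, a hindlimb T-box factor, read 185 in Pdpn KO replicate 1 and 517 in replicate 2, against 165 and 185 in WT, and Pitx1, which acts upstream of Tbx4, read 255 and 564 against 276 and 333. Hoxc10, a Hox gene of the hindlimb and lumbar trunk, read 81.5 and 418 against 205 and 172, and Hoxd13, of the distal limb, 514 and 1534 against 483 and 491. With 1 array of each kind these differences have no replicate.

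Genes around Pdpn on chromosome 4 held more small p-values than other stretches of the genome. Among the 100 measured genes on each side, 10 had an unadjusted p under 0.01, all distal to Pdpn, against 0.447% of other genes (Fisher's exact test, two-sided p = 5.52e-08, genes not being independent); no window of the same size on another chromosome held over 6, which argues against chance placement. None of the 10 was among the 20 measured genes nearest to Pdpn (count 0), but of the 10 nearest on the distal side only 1 was brighter than the median gene, so an effect of the targeted allele on its nearest genes stays open. A candidate explanation is DNA of another strain carried with the targeted allele: 3 of the 10 were higher, among them Fv1, a retroviral restriction gene with different alleles in different mouse strains (0.77 ± 0.13), and Angptl7 (2.29 ± 0.48), and 7 were lower, among them Zfp979, Zfp982 and Nppb. This cannot be told apart from a response to the loss of podoplanin without genotypes of the flanking DNA, and a strain variant may alter expression or only the fit of a probe; Decr1 and Penk lie 914 and 954 measured genes away, near the other end of the chromosome, and are not covered by these tests.

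Both positional lists that passed had smaller medians in Pdpn KO replicate 1 than in Pdpn KO replicate 2, 0.08 against 0.59 for the posterior Hox genes and 0.04 against 0.12 for the other factors, and the difference between the lists was not tested. The posterior Hox list lost its call without Pdpn KO replicate 2 (adjusted p = 0.452), but 8 of its 16 genes had both Pdpn KO values above both WT values, against 16.7% by chance, so dependence on that array alone stays open. The other factors still passed without it at the preset correlation (adjusted p = 0.0127), which argues only against that array as their whole source, and with all 4 arrays they did not pass at an estimated correlation (adjusted p = 0.813). For Pdpn KO replicate 2, a culture that held another part or stage of the embryo may account for the Hox values: anterior Hox genes were lower there than in Pdpn KO replicate 1 by a median log2 difference of -0.77, with 10 of 14 lower, and 13 of 16 posterior genes were higher. That explanation stays open because 4 anterior genes were not lower, the 2 cultures also differ in sex, and no source used here gives the stage or tissue of each culture; an effect of genotype on the positional factors high in both arrays is open too.

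Pdpn KO replicate 2 has the sex-linked pattern of female cells and the other 3 arrays that of male cells, which the label of female for all 4 does not describe. An exchange of this array with a WT array is argued against by its Pdpn intensity of 201.0, far below the WT values. Embryos of both sexes in each culture are argued against as well, because the highest Xist intensity of the other 3 arrays was 3.14% of that in Pdpn KO replicate 2. The sex difference is not the source of the genes past the threshold: both lie on chromosome 4, and without Pdpn KO replicate 2 the log2 fold change of Decr1 was -1.97. No biological explanation of the sex pattern was tested, and the difference in sex stays open for the list shifts that rest on this array.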
